A study of Mus musculus with 6 samples.

How the data were processed

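Expression was measured by RNA sequencing of total RNA from repair tissue of 6 samples, 3 Empty-lip and 3 Clod-lip, grouped by their titles. Per the submitters' processing notes, TopHat and the mouse build mm10 were used, with no version given; the tools that made the expression values and the comparison are not given in the sources used here. The authors deposited FPKM per sample for 23351 genes, with group means, and their own comparison, in which a log2 fold change, a test score, a p-value and a q-value are given per gene. The deposited values are named FPKM, a unit scaled by transcript length and by mapped fragments, so they are not counts and no count test was run. The deposited log2 fold change column holds 561 cells with text in place of a number and was not used as a number. The authors tested 10783 genes, and marked 12417 as not tested and 151 as having low data; their smallest p-value is 5e-05, and the largest q-value among their 1318 calls is 0.0499. A total of 101 entries join the symbols of several genes, 1 line was emptied before the data were used here, and 6482 genes are listed at 0 in all samples.

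Read counts were not used here, so absolute depth and counting intervals were not derived. In low FPKM values, up to 0.5, the ratios between libraries fell on ratios of whole numbers up to 6, within 0.5%, for 87.4% to 90.2% of genes, against 8.58% to 11.4% with the unit shifted. This placed the depth relative to Empty-lip 1 at 1.07, 1.13, 1.06, 0.994 and 1.10 for Empty-lip 2, Empty-lip 3, Clod-lip 1, Clod-lip 2 and Clod-lip 3. Whether the values were also scaled between libraries is not known, and such a scaling would enter these figures. The length correction gives very short genes very large values: 16 small RNA genes pass 1000 FPKM in some library, Mir451 among them, and Mir140 and Mir128-1 both have 24561.5 FPKM in Empty-lip 2. Of 26 genes listed at 0 in some libraries and averaging at least 10 FPKM in the others, 24 are small RNA genes. An exact 0 is therefore reported as listed at 0 only. Mirlet7i passed while listed at 0 in all 3 Clod-lip libraries, and 1110035M17Rik, 1700084E18Rik and Lypd2 passed while listed at 0 in all 3 Empty-lip libraries; no fold is given for these 4 genes.

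Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trend in the prior variance, over the 13408 genes with a mean of at least 0.5 FPKM, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of low genes. The design, the alternatives, the rule for named genes and 26 gene lists were fixed before the data were examined. The rule takes Adgre1, Csf1r, Cd68, Cd163 and Mrc1; the 10 largest rises and 10 largest falls among passing genes of at least 1 FPKM in a group and not listed at 0; and up to 4 members of each list by smallest p, or the 2 of highest value where none passes. Lists were tested with camera against all other genes, with a preset correlation of 0.01 and with an estimated correlation, and with fry. Of 490 list entries, 484 matched a symbol of the table, older symbols included. Values of single libraries were compared with exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1. On simulated data with 200 of 13408 genes changed, over 5 simulations of Clod-lip against Empty-lip, the test recovered 77.6% of genes changed by 2-fold and 95% of those changed by 4-fold, with 9.2 false calls on average. The changed genes had a mean log2(FPKM + 1) above 1. The simulated noise was independent between genes and left out shifts shared by the genes of a library, so these rates need not hold for the real data.

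Gene positions come from the GENCODE annotation of the same build, in which 99.1% of 21608 genes with a single match overlap the deposited position. Pearson correlations of log2(FPKM + 1) between libraries ran from 0.950 to 0.977, and no pair of libraries was identical. Labels give no batch. Alternatives were the replicate number as a block, each library left out in turn, pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, quantile normalization and limma without trend. Leaving out Empty-lip 1 with Clod-lip 2, leaving out small RNA genes with joined entries, and camera with an estimated correlation as a separate setting were added after seeing the data. The alternatives written for a table holding group values only were not needed.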

Results

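Repair tissue was taken from C57BL/6 mice at the surface of injured bone, as periosteum together with quadriceps muscle, after injection of liposomes. The 3 Empty-lip libraries are taken here as the liposome control and the 3 Clod-lip libraries as clodronate liposomes, which deplete phagocytic cells. The series title names a search for factors from macrophages related to blood vessel growth and wound healing, so the comparison of Clod-lip with Empty-lip asks which transcripts differ when macrophages are targeted. Expression was given as FPKM, fragments scaled by transcript length and by the mapped fragments of the library, for 23351 genes. Setting aside microRNA and small nucleolar RNA genes, the FPKM of a library summed to between 561414 and 606630. Those small RNA genes took 45.1%, 39.1% and 47.7% of all FPKM in Empty-lip 1, 2 and 3, against 32.7%, 0.189% and 0.0985% in Clod-lip 1, 2 and 3. Read counts were not used here. If no further scaling between libraries was applied, the steps between low FPKM values placed their depth between 0.994 and 1.13 times that of Empty-lip 1. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

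Of 5 macrophage genes fixed as a check of the labels, 1 fell in Clod-lip and 4 did not pass, and of 27 macrophage markers 4 fell. As a list the markers lay lower by camera with the preset correlation, with adjusted p = 0.553 with an estimated correlation. Mrc1, the mannose receptor, fell from 123 ± 4.67 to 69.6 ± 18.9 FPKM (SD, n = 3 libraries each), a log2 change of -0.85 ± 0.17 (SE) with a limma adjusted p of 0.0394. Mrc1 alone of the 5 passed. Emr1, the file's symbol for Adgre1, which encodes the F4/80 antigen, stood at 136 ± 6.23 FPKM in Empty-lip and 106 ± 33.4 FPKM in Clod-lip (log2 -0.40, limma adjusted p = 0.277). Csf1r, the receptor for colony stimulating factor, stood at 148 ± 1.80 against 115 ± 30.8 FPKM (log2 -0.40, limma adjusted p = 0.218).

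The other check genes did not pass either. Cd68 stood at 398 ± 66.8 FPKM in Empty-lip and 282 ± 39.9 FPKM in Clod-lip (log2 -0.49, limma adjusted p = 0.114). Cd163, a scavenger receptor for haemoglobin complexes, stood at 18.2 ± 1.14 and 20.8 ± 7.20 FPKM (log2 0.14, limma adjusted p = 0.749). Clod-lip 2 lay above the 3 Empty-lip libraries for Emr1, at 144 FPKM, and within their range for Csf1r, at 149 FPKM, whereas Clod-lip 1 and 3 held 82.8 and 90.5 FPKM of Emr1. Per the authors' deposited table, q was 0.0427 for Emr1, 0.0288 for Csf1r and 0.00382 for Cd68. On mm10, Emr1 lies on chromosome 17 from 57358691 to 57483527, Csf1r on chromosome 18 from 61100598 to 61132149 and Mrc1 on chromosome 2 from 14229392 to 14332057.

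Of 27 macrophage markers tested, 4 fell, 0 rose and 23 did not pass, and 15 fell when adjusted over the list alone. The largest of the passing changes was that of Fcgr1, the high affinity Fc gamma receptor, which fell from 91.0 ± 6.77 to 32.9 ± 17.4 FPKM (log2 -1.55 ± 0.29, limma adjusted p = 0.0360). Lgmn, which encodes the lysosomal protease legumain, fell from 787 ± 53.1 to 487 ± 81.3 FPKM, and Mertk, a receptor for apoptotic cells, fell with a log2 change of -0.39 ± 0.08. The median over the list was -0.54, and 25 of the 27 genes had a negative log2 change. The list lay below the other genes by camera (adjusted p = 5.69e-09 with the preset correlation, adjusted p = 0.553 with an estimated correlation). The mean of the list relative to Empty-lip was -0.70 in Clod-lip 1, -0.09 in Clod-lip 2 and -0.82 in Clod-lip 3. Without Clod-lip 2 the median was -0.70.

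**Figure D1:**
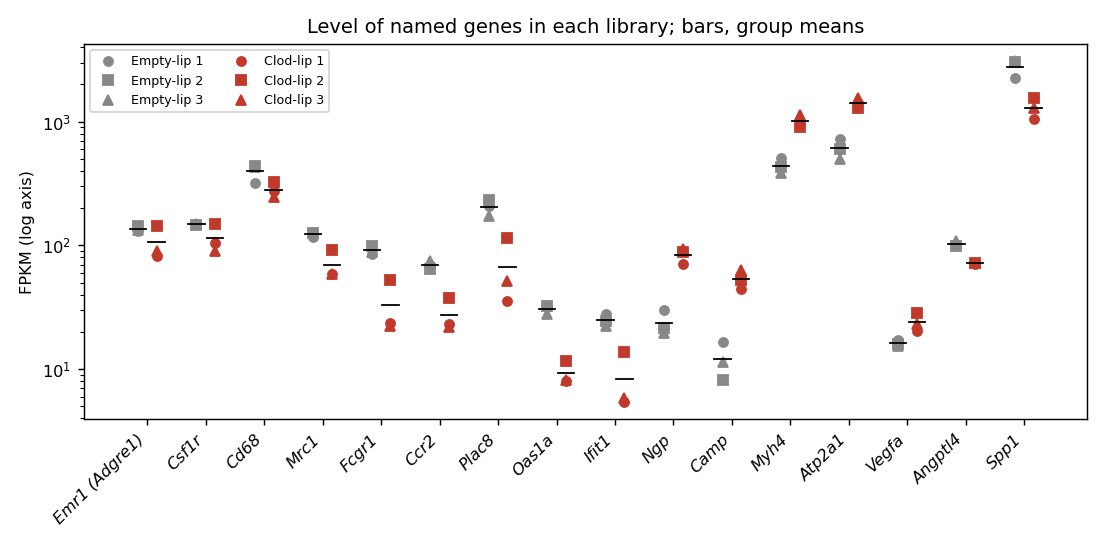
FPKM of 16 genes on a log axis, with 1 point per library (grey, Empty-lip; red, Clod-lip; symbol shape, library number) and a bar at each group mean. Clod-lip 2 lies at 144 FPKM of Emr1, just above the Empty-lip libraries, whereas all 3 Clod-lip libraries lie below all 3 Empty-lip libraries for Mrc1, Fcgr1, Ccr2 and Oas1a.

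Over the whole transcriptome, granule genes of developing granulocytes were among those with the largest rises, and genes induced by interferon among those with the largest falls. Of 24 contractile genes of skeletal muscle, 18 rose and 6 did not pass (adjusted p = 0.553 for the list by camera with an estimated correlation). By limma on log2(FPKM + 1), 543 of 13408 genes passed at a Benjamini-Hochberg adjusted p of 0.05 or less, 381 higher and 162 lower in Clod-lip. Of these, 95 rose and 44 fell by at least 2-fold on that scale. At an unadjusted p under 0.05 there were 2917 genes. The groups did not overlap for 27.4% of genes tested, against 10% on average by chance. Genes move together within a library, so a single grouping can lie far from that average. The authors' deposited table called 1318 genes, 735 higher and 583 lower in Clod-lip, and called 481 of the 543 in the same direction. The count rested on single libraries: it was 269 without Empty-lip 1, 2 without Empty-lip 2, 85 without Empty-lip 3, 30 without Clod-lip 1, 1392 without Clod-lip 2 and 16 without Clod-lip 3. Of the 48 passing genes that the fixed rule names, all kept their direction in each of these, as is likely for genes that passed on the same libraries, and 21, 0, 14, 7, 48 and 5 kept their call, in the same order. Without Empty-lip 1 and Clod-lip 2, the 2 libraries with the most S100a8, it was 1101, with 489 higher and 612 lower, an alternative chosen after seeing the data.

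**Figure D2:**
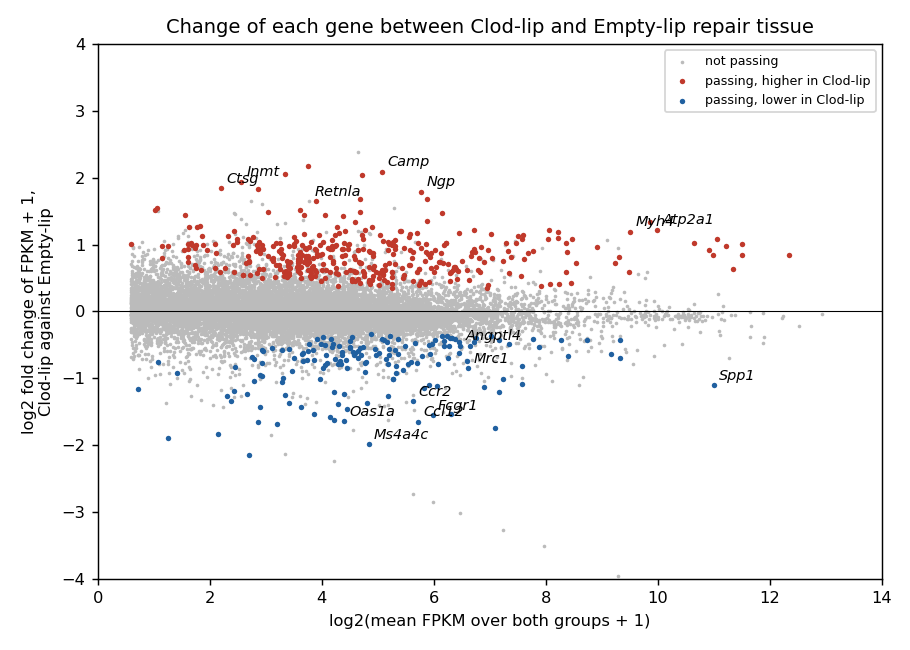
Log2 change between Clod-lip and Empty-lip against the log2 of mean FPKM + 1, with 1 point per gene tested (red, passing and higher; blue, passing and lower; grey, not passing); 12 genes lie outside the vertical axis. Ngp and Camp stand among the rises with log2 changes of 1.79 and 2.09, and Ms4a4c among the falls with -1.99.

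Among the 10 largest rises were 5 genes of granulocyte granules. Camp, the cathelicidin precursor, rose from 12.1 ± 4.31 to 53.2 ± 9.46 FPKM (log2 2.09 ± 0.24, limma adjusted p = 0.0123). Ngp, neutrophilic granule protein, rose from 23.8 ± 5.40 to 83.9 ± 11.6 FPKM (log2 1.79 ± 0.17, limma adjusted p = 0.00801). Elane, neutrophil elastase, Ctsg, cathepsin G, and Prtn3, proteinase 3, had log2 changes of 2.06, 1.85 and 1.83, from means of 3.05, 1.01 and 2.27 FPKM in Empty-lip. Per the authors' deposited table, q was 0.814 for Elane and 0.837 for Prtn3. Lrrc30 rose with a log2 change of 2.18, Mylk4, a myosin light chain kinase, with 2.04, Inmt, a methyltransferase, with 1.94, and Ppp1r3c, a glycogen targeting subunit of a phosphatase, with 1.68. The joined entry for Hba-a1 and Hba-a2, alpha globin genes that share reads, went from 0.286 ± 0.381 to 113 ± 84.6 FPKM and is uncertain, since Hba-a2 has an entry of its own at 214 FPKM in Empty-lip.

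The 10 largest falls were led by Gm9733, from 9.53 ± 0.868 to 1.44 ± 0.685 FPKM (log2 -2.15 ± 0.22, limma adjusted p = 0.00884). Ms4a4c fell from 43.6 ± 2.64 to 11.3 ± 6.44 FPKM (log2 -1.99 ± 0.34, limma adjusted p = 0.0280), and Plac8 from 205 ± 31.0 to 67.3 ± 41.8 FPKM (log2 -1.75 ± 0.37, limma adjusted p = 0.0469). The chemokine gene Ccl12 fell with a log2 change of -1.65. Oas3, Oas1a and Mx1, antiviral effectors induced by interferon, fell with -1.68, -1.64 and -1.66, Pyhin1 with -1.62, Gm14446 with -1.84 and Raet1e with -1.90. Gm9733, Gm14446, Raet1e, Ms4a4c and the Oas genes belong to families of similar copies, so reads shared between copies leave their values uncertain.

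Interferon response genes were the list with the lowest median. Of 18 tested, 8 fell, 0 rose and 10 did not pass, with 16 falling when adjusted over the list alone. The median log2 change was -1.39, and all 18 had a negative sign. Oas1a fell from 30.6 ± 2.32 to 9.26 ± 2.03 FPKM (log2 -1.64 ± 0.14, limma adjusted p = 0.00602), Rsad2, the antiviral protein viperin, from 26.9 ± 0.745 to 10.2 ± 4.29 FPKM, and Ifit1 with a log2 change of -1.59 ± 0.30. The list passed camera with the preset correlation (adjusted p = 2.58e-12), with adjusted p = 0.553 with an estimated correlation. Its mean relative to Empty-lip was -1.69 in Clod-lip 1, -0.55 in Clod-lip 2 and -1.38 in Clod-lip 3.

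Monocyte markers moved unevenly. Of 10 tested, 2 fell, 0 rose and 8 did not pass, and 3 fell and 1 rose when adjusted over the list alone. Ccr2, the receptor by which monocytes leave marrow, fell from 69.4 ± 5.37 to 27.5 ± 8.77 FPKM (log2 -1.34 ± 0.19, limma adjusted p = 0.0176), while Ly6c2 had a log2 change of -1.48 and Ace one of 0.38, neither passing. The median was -0.52 (camera adjusted p = 0.0457; adjusted p = 0.609 with an estimated correlation). The camera call was lost without Empty-lip 1, with a median of -0.35, without Empty-lip 2 (-0.57), without Clod-lip 1 (-0.27) and without Clod-lip 3 (-0.39), and the median was -0.95 without Clod-lip 2.

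Lysosome genes shared the direction of the macrophage markers. Of 18 tested, 1 fell, 0 rose and 17 did not pass, and 13 fell when adjusted over the list alone. Gla, alpha-galactosidase A, fell from 27.5 ± 2.37 to 17.7 ± 2.94 FPKM (log2 -0.61 ± 0.13, limma adjusted p = 0.0452), and Ctsl and Ctsb, lysosomal cathepsins, had log2 changes of -0.57 and -0.50 without passing. The median was -0.36 (camera adjusted p = 1.59e-08; adjusted p = 0.553 with an estimated correlation).

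Of 29 chemokine and cytokine genes tested, 5 fell, 0 rose and 24 did not pass, and 7 fell when adjusted over the list alone. Ccl2, a chemoattractant of monocytes, fell with a log2 change of -0.82 ± 0.13 (limma adjusted p = 0.0230), Ccl7 from 201 ± 49.5 to 99.6 ± 25.5 FPKM and Cxcl10, a chemokine induced by interferon, from 30.2 ± 2.74 to 11.3 ± 6.52 FPKM. The median was -0.20 (camera adjusted p = 0.0339; adjusted p = 0.724 with an estimated correlation). Empty-lip 1 and Clod-lip 2 stood apart in this list, with means of 0.51 and 0.91 relative to Empty-lip, against -0.98 in Clod-lip 1 and -0.68 in Clod-lip 3. The call was lost without Empty-lip 1 (median -0.28), without Clod-lip 1 (0.06) and without Clod-lip 3 (0.12), and the median was -0.88 without Clod-lip 2.

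Of 24 contractile genes of skeletal muscle tested, 18 rose, 0 fell and 6 did not pass, with 20 rising when adjusted over the list alone. Myh4, a myosin heavy chain of fast fibres, rose from 442 ± 62.3 to 1008 ± 119 FPKM (log2 1.19 ± 0.13, limma adjusted p = 0.0123). Atp2a1, the calcium pump of fast fibres, had a log2 change of 1.22, Pygm, muscle glycogen phosphorylase, one of 1.19, and Actn3 one of 0.96. The 6 that did not pass, named after their values were seen, were Ttn (log2 0.69), the slow fibre myosin genes Myl2 (1.01) and Myh7 (0.20), and the slow fibre troponin genes Tnni1 (-0.24), Tnnt1 (-0.21) and Tnnc1 (-0.09). The median was 0.99 (camera adjusted p = 9.15e-17; adjusted p = 0.553 with an estimated correlation). These 24 genes made up 2.81 ± 0.451% of FPKM other than that of small RNA genes in Empty-lip and 5.42 ± 0.430% in Clod-lip (SD, n = 3 each), a 1.93-fold difference with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. Of 16 muscle regeneration genes tested, 0 rose, 0 fell and 16 did not pass (median 0.00, from -0.20 without Empty-lip 2 to 0.11 without Clod-lip 2; camera adjusted p = 0.943), with list means of 0.27, -0.29 and -0.02 in Clod-lip 1, 2 and 3, and with Myog, a transcription factor of differentiating muscle, at a log2 change of -0.14 ± 0.26.

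Of 19 neutrophil markers tested, 6 rose, 0 fell and 13 did not pass, and 6 rose when adjusted over the list alone. The 13 included Lcn2 and Mmp8, also granule genes, with log2 changes of 0.99 and 0.13, named after their values were seen. Ltf, lactoferrin, rose from 6.23 ± 2.03 to 21.6 ± 4.76 FPKM (log2 1.66 ± 0.22, limma adjusted p = 0.0163), beside Ngp, Camp and Prtn3. The median was 0.95 (camera adjusted p = 0.000441; adjusted p = 0.591 with an estimated correlation). Clod-lip 2 stood apart with a mean of 1.63 relative to Empty-lip, against 0.17 in Clod-lip 1 and 0.52 in Clod-lip 3, and Empty-lip 1 stood at 0.66. S100a8, a calcium binding protein abundant in neutrophils, was at 1608 FPKM in Clod-lip 2 and 644 FPKM in Empty-lip 1, and between 258 and 549 FPKM in the other libraries (exact two-sided permutation p = 0.3 between groups). Without Clod-lip 2 the list had a median of 0.36 and no longer passed, and without Empty-lip 3 the median was 0.27.

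In 2 lists fixed in advance that relate to the study's title, few genes passed here. Per the authors' deposited table, 3 angiogenic genes were called higher and 1 lower, and 5 secreted factors higher and 7 lower. That table called 1318 of the 10783 genes the authors tested. Of 30 angiogenic factors and receptors, 1 fell, 0 rose and 29 did not pass, with 2 rising and 1 falling when adjusted over the list alone (median 0.14, camera adjusted p = 0.0966). The median was 0.08 without Empty-lip 2 and 0.08 without Clod-lip 3. Angptl4, an inhibitor of lipoprotein lipase, fell from 103 ± 5.46 to 71.8 ± 0.606 FPKM (log2 -0.51 ± 0.07, limma adjusted p = 0.0163). Vegfa, the main growth factor of blood vessels, stood at 16.2 ± 0.878 and 23.9 ± 3.96 FPKM (log2 0.53, limma adjusted p = 0.0599), and Tek, the angiopoietin receptor, at 9.60 ± 0.900 and 14.1 ± 1.40 FPKM (log2 0.51, limma adjusted p = 0.0512). Per the authors' deposited table, q was 0.00443 for Vegfa and 0.00314 for Tek. Of 30 secreted factors of macrophages, 1 fell, 0 rose and 29 did not pass, and 3 fell and 3 rose when adjusted over the list alone (median -0.17, camera adjusted p = 0.270). The median was -0.09 without Clod-lip 1 and -0.28 without Clod-lip 2, and the list passed without Empty-lip 1 and Clod-lip 2 together (median -0.30), an alternative chosen after seeing the data. Spp1, osteopontin, fell from 2789 ± 458 to 1299 ± 249 FPKM (log2 -1.11 ± 0.18, limma adjusted p = 0.0232), and was the 1 gene to pass also among 16 macrophage activation genes and among 14 osteoblast and osteocyte markers. Retnla, a marker of alternative activation, stood at 5.91 ± 3.09 and 19.4 ± 5.93 FPKM (log2 1.65, limma adjusted p = 0.0559).

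Among markers of other resident cells, pericyte, adipocyte and endothelial lists lay higher in Clod-lip by camera with the preset correlation, with few genes passing, while fibroblast and osteoblast lists did not pass (camera adjusted p = 0.132 and 0.123). Of 12 pericyte and smooth muscle markers, 1 rose, 0 fell and 11 did not pass, and 3 rose when adjusted over the list alone (median 0.37, camera adjusted p = 0.000835; adjusted p = 0.591 with an estimated correlation). Abcc9, a channel subunit, rose from 8.66 ± 1.02 to 15.1 ± 2.32 FPKM, and without Clod-lip 3 the median of the list was 0.22. All 12 log2 changes were positive, from 0.07 for Pdgfrb to 0.73 for Abcc9. Whether transcripts of muscle fibres add to the values of these resident cell markers was not tested. Of 12 adipocyte markers, 0 passed and 4 rose when adjusted over the list alone (median 0.36, camera adjusted p = 0.00256; adjusted p = 0.591 with an estimated correlation), with Fabp4 at 646 ± 76.6 and 957 ± 125 FPKM. Of 18 endothelial markers, 0 passed and 1 rose when adjusted over the list alone (median 0.21, camera adjusted p = 0.00256; adjusted p = 0.591 with an estimated correlation), with Pecam1 at 75.5 ± 10.4 and 87.8 ± 5.39 FPKM. The adipocyte call was lost without Clod-lip 3 (median 0.23) and the endothelial call without Empty-lip 2 (median 0.13). The share of contractile genes, 2.81% and 5.42% by group, moved in the same direction.

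Cartilage and nerve markers passed camera with 0 genes passing of 8 and of 9 tested. Their medians were 0.35 (camera adjusted p = 0.0393) and 0.45 (camera adjusted p = 0.0453), both with adjusted p = 0.553 with an estimated correlation. Adjusted over the list alone, 0 cartilage markers passed, and 3 nerve and Schwann cell markers rose and 1 fell. Comp, a cartilage matrix protein, stood at 30.1 ± 4.74 and 39.5 ± 5.53 FPKM, and Pmp22, a myelin protein, at 64.1 ± 7.46 and 66.3 ± 3.75 FPKM. Both calls were lost without Empty-lip 1 (medians 0.33 and 0.42), without Clod-lip 2 (0.33 and 0.48) and without Clod-lip 3 (0.39 and 0.32). They were also lost with members of at least 5 FPKM (0.38 and 0.21), which leaves fewer genes in each list, and without Empty-lip 1 and Clod-lip 2 together (0.20 and 0.42).

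Of 9 osteoclast markers tested, 2 fell, 0 rose and 7 did not pass, and 2 fell when adjusted over the list alone. Acp5, tartrate resistant acid phosphatase, fell from 50.9 ± 4.87 to 26.8 ± 6.44 FPKM (log2 -0.92 ± 0.16, limma adjusted p = 0.0285), and Tnfrsf11a, the receptor RANK, from 8.08 ± 0.740 to 5.08 ± 0.484 FPKM, whereas Ctsk, cathepsin K, stood at 71.8 ± 2.88 and 67.3 ± 4.56 FPKM without passing. The median was -0.13 (camera adjusted p = 0.0284; adjusted p = 0.553 with an estimated correlation), and the call was lost without Empty-lip 1 (median -0.08) and without Clod-lip 1 (median -0.20). Cell cycle genes had 22 negative signs of 22 tested with 0 genes passing, also when adjusted over the list alone, and a median of -0.18 (camera adjusted p = 0.000752; adjusted p = 0.591 with an estimated correlation). Ube2c stood at 86.7 ± 9.84 and 67.6 ± 3.65 FPKM, and the call was lost without Clod-lip 2 (median -0.11).

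The remaining lists did not pass camera. Of 26 fibroblast and matrix genes, 2 rose, 1 fell and 23 did not pass (camera adjusted p = 0.132), with the small proteoglycan genes Fmod and Aspn rising by log2 changes of 0.74 and 0.62 and Thy1 falling with -0.37. Of 14 osteoblast and osteocyte markers, Spp1 alone passed (median 0.33, camera adjusted p = 0.123), though the list passed without Empty-lip 3 (median 0.36). Of 16 hypoxia response genes, Aldoa, a glycolytic enzyme of muscle, rose with a log2 change of 0.64 and 15 did not pass (median 0.09, camera adjusted p = 0.0966). The hypoxia list passed without Empty-lip 1 (median 0.21) and without Clod-lip 1 (median 0.30), and its median was -0.04 without Empty-lip 3 and -0.11 without Clod-lip 2. Of 11 erythrocyte and megakaryocyte markers, the joined alpha globin entry alone passed (camera adjusted p = 0.149), while Pf4, platelet factor 4, stood at 940 ± 51.9 and 638 ± 145 FPKM. Of 14 fibrinolysis and coagulation genes, Serpine2, a protease inhibitor, rose with 0.36 and 13 did not pass (camera adjusted p = 0.517). Of 15 stress genes, Fosb rose with 0.92 and Hsph1 fell with -0.47, and 13 did not pass (camera adjusted p = 0.955). Macrophage activation genes (camera adjusted p = 0.777), 17 dendritic and mast cell markers (camera adjusted p = 0.802; 0 passing; Cd74 at 377 ± 21.3 and 303 ± 115 FPKM) and 11 lymphocyte markers (camera adjusted p = 0.967; 0 passing; Cd79b at 3.31 ± 0.897 and 3.37 ± 0.839 FPKM) did not pass.

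**Figure D3:**
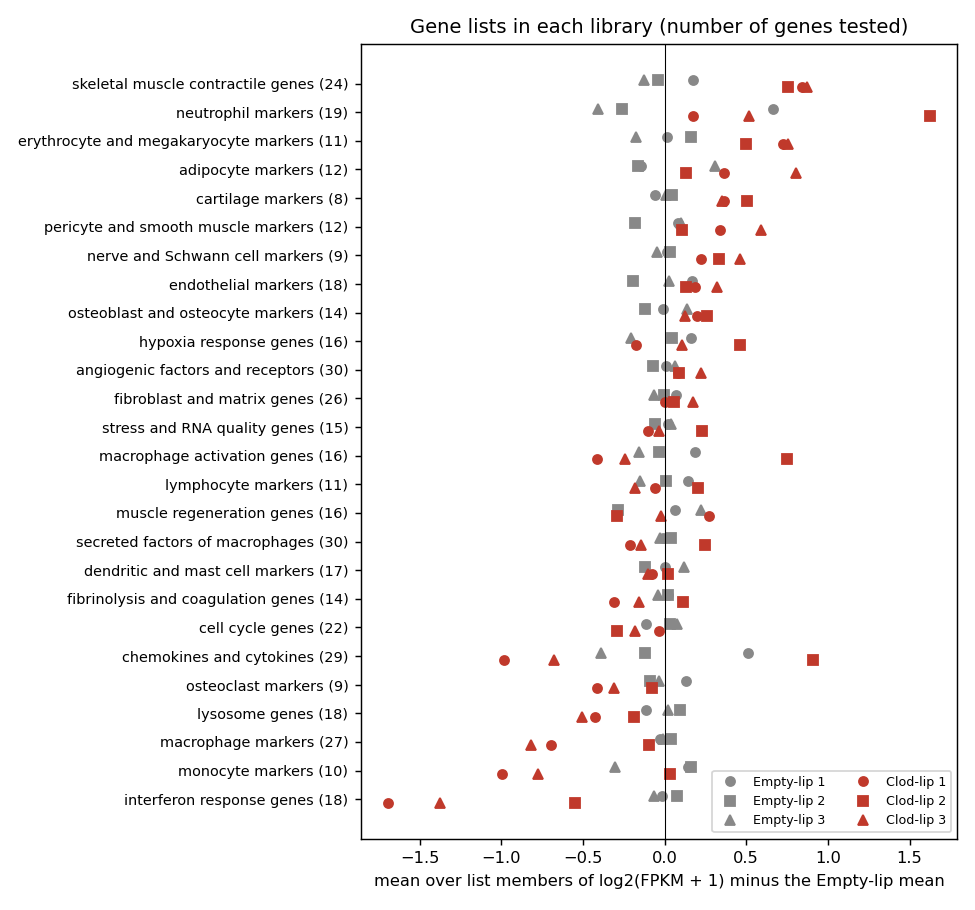
Mean over the tested members of each of 26 gene lists of log2(FPKM + 1), relative to the mean of the Empty-lip libraries, with 1 point per library (grey, Empty-lip; red, Clod-lip; symbol shape, library number). Contractile genes lie between 0.76 and 0.87 in the 3 Clod-lip libraries, while interferon response genes lie at -1.69, -0.55 and -1.38.

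In all, 14 of 26 lists passed camera with the preset correlation, 7 higher and 7 lower in Clod-lip, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.553. By fry, whose p tests whether the genes of a list move on balance in a single direction without comparing them with other genes, 1 list passed, the contractile genes (adjusted p = 0.0357).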

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

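The depth of the libraries was estimated only relative to each other, and 3 libraries per group leave each call open to single libraries. The settings that leave out Empty-lip 1 with Clod-lip 2 or small RNA genes with joined entries, and camera with an estimated correlation, were chosen after seeing the data. The 543 genes kept their direction in each setting that tested them, which is likely by construction for genes that passed on the same libraries. Leaving out each library in turn gave between 2 and 1392 genes, and fewer libraries are part of that change by construction; the cause of the rise without Clod-lip 2 was not tested. The count was 312 with no filter, where more genes are tested, 284 without trend and 1101 without Empty-lip 1 and Clod-lip 2; the cause was not tested for the last pair. It stayed between 521 and 630 with the other pseudocounts, the higher filter, quantile normalization and without small RNA genes and joined entries. Same-numbered libraries deviated with correlations of -0.08, -0.04 and 0.08, which gave no sign that the numbers pair the samples but cannot exclude it. With the replicate number as a block, 170 genes passed, 120 higher and 50 lower, 158 of them shared with the 543. Of the 26 lists, 14 passed camera, between 9 and 15 on leaving out single libraries, with 9 without Clod-lip 3, and 0 with an estimated correlation. The macrophage median ran from -0.70 to -0.40 on leaving out single libraries and kept its call; with an estimated correlation the median of -0.54 had an adjusted p of 0.553. The chemokine median was 0.06 without Clod-lip 1 and 0.12 without Clod-lip 3, with its call lost in both, and ran from -0.88 (without Clod-lip 2) to that value; the cause was not tested. The alternatives for a table with group values only do not apply.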

Other observations

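The tests for the number of genes, for the pooled markers, for the macrophage and monocyte lists, for the 3 monocyte genes and for mature neutrophil genes were chosen after the result was seen; those for mature muscle genes outside the contractile list and for erythroid precursor genes were written before. Groups of genes that share the start of their symbol were chosen after seeing the data. Of 29 such families, 13 passed camera with the preset correlation, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.473. Of 45 Nduf genes, subunits of respiratory complex I, 1 rose, 0 fell and 41 had a positive log2 change (median 0.20, camera adjusted p = 1.86e-07; adjusted p = 0.473 with an estimated correlation). Of 17 Atp5 genes, subunits of ATP synthase, 1 rose, 0 fell and 17 were positive (median 0.17, camera adjusted p = 0.000318; adjusted p = 0.473 with an estimated correlation). Of 16 Cox genes 2 rose, Cox6a2 and Cox8b, both also among the mature muscle genes tested separately (camera adjusted p = 0.000923; adjusted p = 0.473 with an estimated correlation). These families moved in the direction of the contractile genes, whose median was 0.99, and of mature muscle genes outside that list, whose median was 1.02. Of 10 Tlr genes, receptors for microbial products, 3 fell, among them Tlr7 and Tlr13 (median -0.59, camera adjusted p = 0.000492; adjusted p = 0.473 with an estimated correlation). Of 5 Fcgr genes 1 fell (median -0.92, camera adjusted p = 0.00232, and adjusted p = 0.473 with an estimated correlation). That gene was Fcgr1, which is also in the macrophage list. The Tlr and Fcgr families moved in the direction of the macrophage markers, whose median was -0.54.

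The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 543 genes and the highest of the others 1 gene, and 1 of the 10 splits, the real one, gave as many genes.

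The mean of the contractile list was higher in all 3 Clod-lip libraries, at 0.84, 0.76 and 0.87 relative to Empty-lip, with 18 of 24 genes rising (adjusted p = 0.553 with an estimated correlation). A smaller share of immune cells would raise the markers of every remaining cell type alike. The contractile list mean lay 0.575 ± 0.0685 (SD over the 3 Clod-lip libraries) above that of 98 pooled markers of other resident types. This SD leaves out the spread of the Empty-lip libraries, whose contractile list means were 0.17, -0.04 and -0.13. This comparison was chosen after the contractile list was seen to have the highest median of the 26 lists. Fold changes of low genes are also understated on this scale. The gap therefore does not decide whether a smaller immune share is the whole cause. More mature muscle fibre in the Clod-lip samples is a candidate explanation: the 22 mature muscle genes outside the list had a median log2 change of 1.02, 22 positive and 19 passing. Both sets mark mature muscle, so a joint rise was likely, and it does not separate more fibre from higher expression per fibre. The slow fibre genes of the contractile list did not pass, with Myl2 at 1.01, Myh7 at 0.20, Tnni1 at -0.24, Tnnt1 at -0.21 and Tnnc1 at -0.09. Whether such a difference came from how tissue was taken or from the treatment was not tested.

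Interferon response genes lay below the macrophage and monocyte lists. They changed by -0.670 ± 0.286 (SD over the 3 Clod-lip libraries) beyond the macrophage list and by -0.627 ± 0.0641 beyond the monocyte list. These SDs leave out the spread of the Empty-lip libraries, whose monocyte list means were 0.14, 0.16 and -0.31. These comparisons were chosen after the interferon list was seen to have the lowest median of the 26 lists. Monocyte markers were also spread, with quartiles of -1.15 and -0.37. The gaps therefore do not decide whether loss of either population, as marked by these lists and at equal content per cell, is the whole cause. A loss of a monocyte subset may also account for the fall, since the interferon list fell less than Ccr2, Ly6c2 and Plac8. The difference was 0.317 ± 0.160 (SD over the 3 Clod-lip libraries). Those 3 genes were picked because they were low, so this cannot be told apart from a weaker interferon response in the remaining cells. A weaker response per cell stays open and was not tested.

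Granule genes of developing granulocytes, 8 genes picked because they had risen, had a median log2 change of 1.81. They exceeded the 4 surface and receptor genes of mature neutrophils not seen before, Fpr1, Fpr2, Mmp25 and Cd177, by 1.66 ± 0.912 (SD over the 3 Clod-lip libraries). This SD leaves out the spread of the Empty-lip libraries. The gap was under 2 SD and does not exclude more mature neutrophils as a cause. Against them, those 4 genes had means of -0.76, 1.28 and -0.15 in Clod-lip 1, 2 and 3, and all 8 surface genes, 4 of them seen before, had means of -0.80, 0.99 and -0.23 with 0 passing, where granule genes had 1.60, 1.91 and 1.84, so Clod-lip 2 widens the SD. Bone marrow in the samples may contribute: 6 erythroid precursor genes of at least 1 FPKM had 0.0897 times the median of the granule genes, below the bound of 0.25 that was set in advance to speak against marrow. That bound was a poor one, because 3 of the 6 genes, Fech, Slc25a37 and Tmcc2, stand at 5 FPKM or more in Empty-lip and would hide a small share of marrow; this minimum was chosen after the result was seen. With 3 genes left, marrow cannot be told apart from a release of immature granulocytes into blood, which was not tested.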
